A study of Mus musculus with 3 samples.

How the data were processed

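The data are from a CITE-seq experiment, in which RNA and antibody-bound DNA tags are read from the same droplets. Brains of female C57BL/6 mice without tumours (naive) were compared with brains bearing metastases grown from E0771, a mouse mammary carcinoma line injected into the carotid artery. Per the labels, brains were digested with a papain-based kit and mononuclear cells were enriched on a Percoll gradient. Each brain was stained with the same 6 surface antibodies (CD11b, CD25, CD3e, CD4, CD45 and CD86) and with a hashing antibody of its own, and all brains were pooled into a single 10x Chromium 3' v2 run. The design text speaks of 6 pooled samples, while the files analysed here hold 4 hashing antibodies, 2 for naive brains and 2 for brains with metastases. Nothing beyond the hashing antibodies says that the 4 brains came from separate animals or days, so p-values measure only the spread between these 4 suspensions.

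The deposited RNA table holds raw UMI counts per gene and cell, and a deposited tag table holds raw tag counts per antibody and cell. Neither was normalised by the authors, as their whole-number values and column sums show. Cell Ranger 3.0.2, Seurat 3.0.1 and the mouse build mm10 are named in the submitters' processing notes, and settings are not given in the sources used here. The deposited per-cell table gives the hashing antibody, the condition and a cluster number for each cell, and the percent of mitochondrial UMIs as computed by the authors. All 12421 cells in it carried a single-brain call. Every cell held at least 500 UMIs and at most 24.9% mitochondrial UMIs, and no further filter on cells was applied. The 13 deposited clusters have numbers and no names. The tables pair 31053 genes with symbols, and no gene coordinates were used. Clec7a and Ifi30 were not analysed here.

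Depth differed between conditions. Naive 1 held 572 cells, 1691221 UMIs and a median of 1393.5 UMIs per cell, and naive 2 held 315 cells, 694223 UMIs and a median of 1230. Metastasis 1 held 5360 cells, 45724262 UMIs and a median of 7294, and metastasis 2 held 6174 cells, 57620835 UMIs and a median of 7707.5. The depth gap came mostly from 5 large deposited clusters, with a median of 10601.5 UMIs per cell in the brains with metastases. Outside them the median was 1621 with metastases and 1207 in naive brains. Because the brains were pooled before loading, RNA free in the suspension was common to droplets of all 4 brains.

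Cell types were rebuilt with scanpy 1.11.5. The 5 large clusters (8408 cells) were kept whole and unnamed, as the naming rule below gave them no class. Krt8, on the fixed list of carcinoma markers, was among their leading genes. They may be tumour cells, which the labels do not state. The other clusters were split by mean CD45 tags, at 10 times the mean of the largest cluster, into an immune step of 2598 cells and a non-immune step of 1415 cells. Each step was clustered on 2000 variable genes and 25 principal components, with 15 neighbours, edges of at least 3 shared neighbours (igraph 0.11.9) and a resolution of 1, which gave 18 and 14 clusters. A cluster was called X-like when at least 3 markers of a fixed list were at least 1 log2 unit above the other cells and at 50 CPM, counts scaled to a common total (20 CPM added before the ratio), with 2 of them among its 10 leading genes, or 1 where 80% of the list was detected. Ependymal-like cells were told from choroid plexus-like cells by cilia genes. Clusters in which the 50 leading genes of the large clusters reached 50% of their share there, or in which 10% of cells were called doublets, or with markers of the other step, were called mixed and left out of every class. Scrublet as implemented in scanpy, at an expected rate of 8%, called 227 cells (1.83%) above a score of 0.407, and called cells outside mixed clusters were kept. The graph, the naming thresholds and the ependymal split were revised after clusters were seen. No correction for free RNA was made.

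UMI counts were summed per brain and class, and a class was tested where 2 brains of each condition held at least 20 cells. The tests were edgeR 4.0.16 quasi-likelihood fits in R 4.3.3 with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. CPM values beside a fold change are TMM-scaled, while unscaled CPM are shares of the UMIs of the class. SE is the standard error of the log2 fold change, and SD is over the 2 brains of a condition. The gene lists were tested with camera (limma 3.58.1) at a correlation of 0.01, and again with an estimated correlation. The 19 lists were homeostatic microglia, type I interferon response, interferon gamma response, chemokines, immune checkpoints and suppressive factors, MHC class I, MHC class II, disease-associated microglia, inflammatory cytokines with NF-kB, complement, cell cycle, dissociation and immediate early genes, ribosomal proteins, glycolysis and hypoxia, lipid handling, T cell exhaustion, cytotoxicity, regulatory T cells and naive T cells. At least 3 measured members were needed for a list test. Shares of cells and antibody levels were compared by two-sided exact permutation tests, which cannot give p below 0.333 with 2 brains against 2. Antibody levels are centred log-ratios over the 6 surface antibodies, so they are relative to each other. Microglia-like and monocyte-like cells of the brains with metastases were compared in edgeR with the brain as a block. Differences in response between cell types were tested as interaction terms with no term for the brain, and lists on them at the correlation of 0.01 only. Intervals on shares are 95% Wilson intervals, those on ratios of low counts are exact, and both cover counting error only. A group at 0 was set at 3 UMIs over the group.

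Lists, markers, tests and the rule for named genes were fixed before the data were examined. That rule takes, among genes with adjusted p at most 0.05, at least 10 UMIs per brain on average in the higher condition and no overlap between conditions, the 10 largest rises and 10 largest falls in microglia-like cells (5 and 5 in other types). It adds up to 4 members of each list past the threshold with the smallest p, and Cxcl10, Cd274, Vsir, P2ry12, Tmem119, Cx3cr1, Apoe, Clec7a and Axl in any case. Predicted genes and mitochondrial genes were not named. Single results of 2 genes that the rule takes are not reported, and both stay in the counts and list tests.

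The fits were tried on simulated counts with 200 genes changed. At 4-fold and 2-fold changes, the fit for microglia-like cells recovered 87 and 41 of 100 changed genes (1943 genes), that for endothelial-like cells 78 and 37 (2266 genes), that for choroid plexus-like cells 88 and 43 (4144 genes), and that for microglia-like against monocyte-like cells 82 and 44 (3938 genes). The interaction fits recovered fewer, 29 and 3 for choroid plexus-like cells (4953 genes) and 40 and 8 for endothelial-like cells (2983 genes). Camera found a list simulated at 2-fold in each of the 3 cell types, and called 1 of 12 unchanged lists in endothelial-like cells and 0 in the others. Genes were drawn independently of each other, so this cannot show camera's error rate where the members of a list are correlated.

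Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, each brain left out, equal cell numbers (24 per brain), equal depth (49448 UMIs), only cells without a UMI of 9 marker genes of other types, the authors' cluster 12 as microglia, fry, and other denominators and antibody scales. Chosen after seeing the data were a limit of 2 UMIs of those 9 genes, use of only the microglia-like cluster with all 11 markers, clusters with at least 5 naive cells for the other types, list tests in those types, further denominators, shares without a T cell-like or microglia-like cluster with 10 monocyte markers, and the interactions with choroid plexus-like and endothelial-like cells. The planned interaction between myeloid types was not run because no other myeloid type held 20 cells in 2 naive brains. Microglia without cycling cells were not tested apart, because no such cluster was found. Where a left-out brain leaves a condition with 1 brain, that brain is assumed to vary like the others. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.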

Results

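Single-cell RNA and 6 surface antibodies were measured in cells enriched from the brains of naive mice and of mice carrying E0771 brain metastases. The comparisons follow the series title, which names myeloid cells native to the central nervous system, immune suppression and Cxcl10, a chemokine induced by interferons. Each condition had 2 brains, told apart by hashing antibodies within a single pool. The brains held 572 cells with 1691221 UMIs (naive 1), 315 cells with 694223 UMIs (naive 2), 5360 cells with 45724262 UMIs (metastasis 1) and 6174 cells with 57620835 UMIs (metastasis 2).

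Microglia-like cells made up a larger share of immune cells in naive brains, at 70.1% and 42.9%, and monocyte-like cells a larger share with metastases. Microglia-like cells, named after the resident macrophages of the brain, were 56.5% ± 19.3 of immune cells in naive brains and 8.13% ± 4.19 with metastases (SD, n = 2 each). Without a microglia-like cluster in which monocyte markers were detected, these shares were 52.5% ± 13.6 and 0.999% ± 0.527. Monocyte-like cells, which derive from blood, were 4.72% ± 3.43 (2 and 4 naive cells) and 33.3% ± 6.06 of immune cells, and T cell-like cells were 9.0% ± 5.15 and 10.7% ± 0.263. One T cell-like cluster, with 10 monocyte markers detected, held 0 and 0 naive cells and 59 and 77 with metastases, and without it the T cell-like share with metastases was 4.29% ± 0.245. Conventional dendritic-like and plasmacytoid dendritic-like cells were seen only with metastases, at 15 and 31 cells and at 6 and 20 cells. The naive counts of 0 allow shares of up to 0.524% and 0.952% of each brain's cells. In metastasis 2, the brain with the larger shares, these classes were 0.502% and 0.324% of cells, below both naive limits. Equal shares of all cells in the 2 conditions are thus not excluded. Of all cells, the large unnamed clusters held 10.6% ± 4.6 in naive brains and 72.1% ± 2.12 with metastases. Their naive cells may carry a wrongly assigned hashing tag, as set out below. Choroid plexus-like cells, the epithelium that secretes cerebrospinal fluid, were 26.8% ± 2.53 and 2.46% ± 0.797, endothelial-like cells 22.6% ± 0.339 and 1.66% ± 0.692, and mural-like cells 9.06% ± 0.205 and 0.133% ± 0.05. NK-like cells were 1.30% ± 0.852 and 0.535% ± 0.0447, neutrophil-like cells 1.36% ± 1.67 and 0.156% ± 0.00899, fibroblast-like cells 1.44% ± 0.686 and 0.123% ± 0.0368, and ependymal-like cells 0.0874% ± 0.124 and 0.234% ± 0.173. Immune clusters that stayed unnamed held 2.45% ± 1.48 and 7.73% ± 3.07 of cells, and mixed clusters 13% ± 0.527 and 4.76% ± 0.432. The exact two-sided permutation test gave p = 0.333, the smallest it allows, for 13 of the 15 classes and 0.667 for T cell-like and ependymal-like cells (adjusted p = 0.385 and 0.667), so no share passed. These shares describe the captured suspension. Percoll enrichment and the gap in cells per brain can move them, which was not tested. For shares of all cells, the large clusters in the denominator moved them too. Outside those clusters NK-like cells were 1.43% ± 0.879 in naive brains and 1.92% ± 0.0141 with metastases, the reverse direction. Mixed clusters reversed as well, at 14.5% and 17.1%, and T cell-like cells were 1.63% and 7.05%. The other classes kept their direction.

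**Figure D1:**
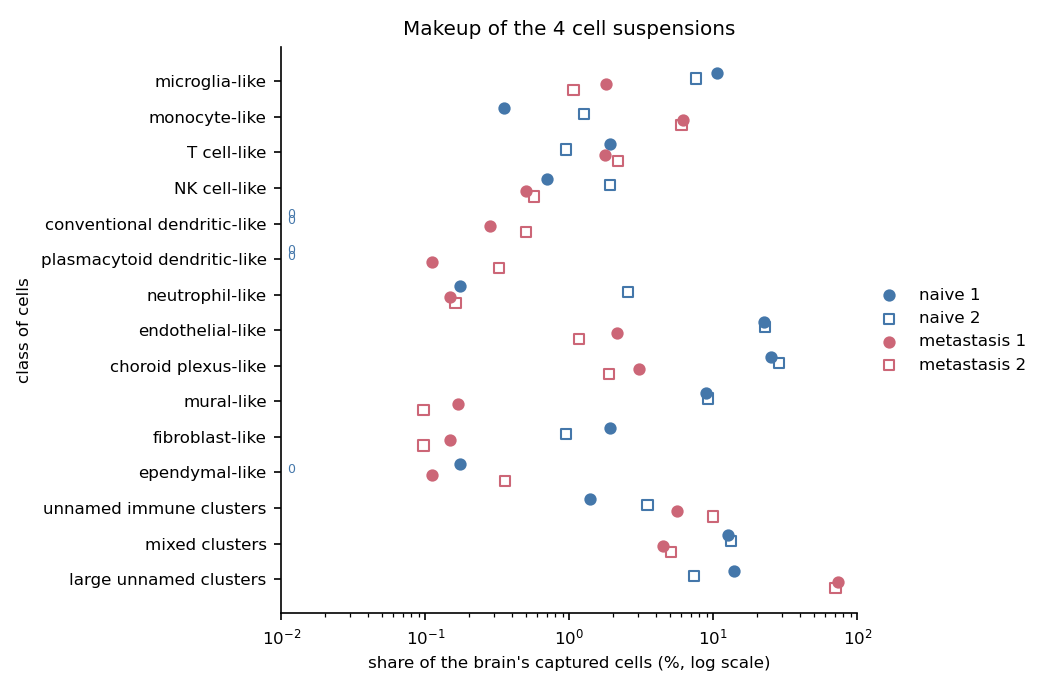
Share of each brain's captured cells (%, log scale, horizontal axis) by class of cells (vertical axis), with a point for each of the 4 brains and 0 printed where a class was not seen. The large unnamed clusters hold 72.1% of cells with metastases and 10.6% in naive brains, while choroid plexus-like, endothelial-like, microglia-like and mural-like cells hold larger shares in naive brains.

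Microglia-like cells of brains with metastases had lower levels of the genes that mark resting microglia. Of 1943 genes tested by edgeR, 278 were higher and 282 lower with metastases, and 746 had an unadjusted p under 0.05. All 19 measured members of the homeostatic list fell (19 also when adjusted over the list alone), with a median log2 fold change of -2.00 (camera adjusted p = 1.1e-24, adjusted p = 0.103 with an estimated correlation). Tmem119, a microglia-specific membrane protein, fell from 2464 ± 233 to 416 ± 14.1 CPM (log2 -2.54, SE 0.21, adjusted p = 1.1e-10; mean ± SD, n = 2). P2ry12, a purine receptor used by surveying microglia, fell from 1489 ± 8.10 to 267 ± 49.5 CPM (log2 -2.44, SE 0.23), and Cx3cr1, the fractalkine receptor, by 1.57 on the log2 scale (SE 0.19). Fcrls (log2 -2.66, SE 0.25), P2ry13 (-3.03, SE 0.56), Crybb1 (-2.89, SE 0.34) and Sparc (-1.90, SE 0.21) fell as well. Other large falls were in Glul, the enzyme that makes glutamine (-2.72, SE 0.24), Pf4 (-2.87, SE 0.55), Slco2b1 (-2.64, SE 0.51), Fscn1 (-2.50, SE 0.37) and Lag3, an inhibitory receptor (-2.50, SE 0.37). In the same sums, the 11 monocyte markers stood at 805 and 263 unscaled CPM in the naive brains and at 6487 and 5203 with metastases, and the 11 microglia markers at 12492 and 13934 against 3516 and 2987. Different clusters held most of the class. A cluster with all 11 microglia markers held 54 and 24 naive cells and 12 and 8 cells with metastases. A second, with 6 microglia markers and all 11 monocyte markers detected, held 7 and 0 naive cells and 85 and 58 with metastases. Conditions did not overlap for 278 of the higher and 280 of the lower genes, and for 63.2% of all genes tested against 33.3% by chance. Counts were 127 higher and 52 lower by DESeq2, 14 and 20 in cells without a UMI of other types' markers, 10 and 25 in the cluster with all 11 markers alone, and 18 and 40 in the authors' cluster 12. Without metastasis 1 they were 175 and 121, and without naive 1, naive 2 or metastasis 2 the lower genes numbered 169, 192 and 171. The homeostatic list remained past the threshold by camera in each of these choices of cells, with adjusted p from 4.1e-31 to 0.103 over 11 alternatives, while the fall was smaller in some of them. The 11 microglia markers went from 13296 and 13934 to 7873 and 7816 unscaled CPM in the cluster with all 11 markers, and from 14860 and 14726 to 7327 and 5496 without other types' markers, and Tmem119 was at log2 -1.38 and -1.67. In these same sets of cells the monocyte markers stood at 736 and 263 in naive brains against 567 and 920 with metastases (all 11 markers), and at 48.5 and 107 against 1034 and 149 (without other types' markers). P2ry12 lost its call in the cluster with all 11 markers (log2 -1.20, adjusted p = 0.0618; range over its alternatives up to that value), and Cx3cr1 in cells without other types' markers (-1.18, adjusted p = 0.0660, the highest of its alternatives). Fscn1 did not keep its call in every alternative (log2 -2.59 to -0.63 over 10), nor did Sparc, Crybb1, Pf4, Slco2b1 and Lag3.

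**Figure D2:**
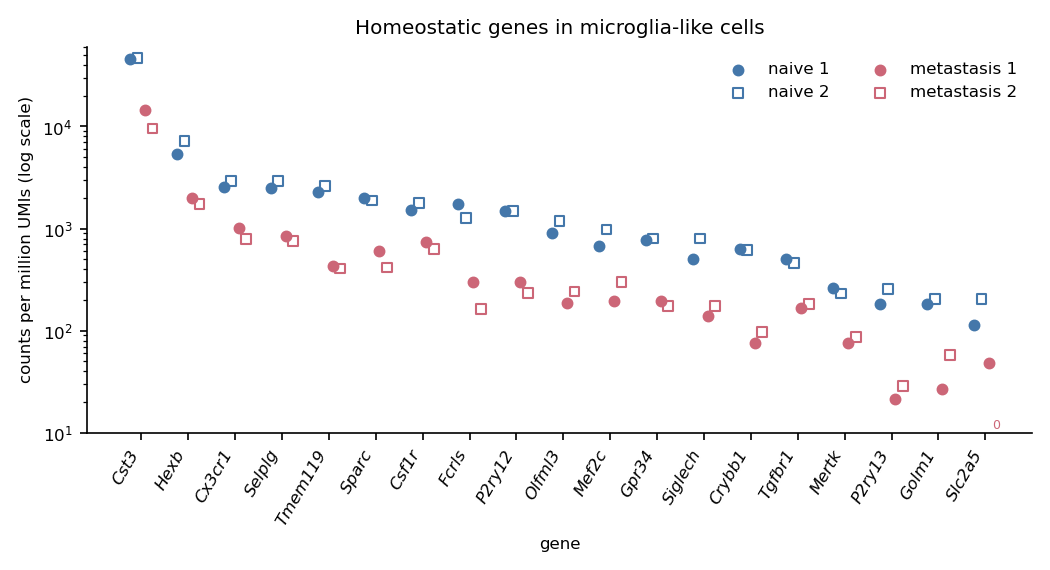
Levels of the measured homeostatic microglia genes in microglia-like cells (CPM, log scale) for each of the 4 brains, with 0 printed for Slc2a5 in metastasis 2. Each gene lies lower in both brains with metastases than in both naive brains, with Tmem119 at 2464 CPM on average in naive brains and 416 with metastases.

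Interferon-induced genes were higher in microglia-like cells with metastases. Of 16 measured members of the type I interferon list, 15 rose (16 when adjusted over the list alone), with a median log2 fold change of 3.05 (camera adjusted p = 2.6e-14, adjusted p = 0.284 with an estimated correlation). Isg15, a ubiquitin-like protein, rose from 101 ± 33.4 to 1496 ± 36.3 CPM (log2 3.76, SE 0.31). Irf7, a transcription factor of the response, rose by 3.47 (SE 0.37), Ifitm3, which blocks viral entry, by 2.42 (SE 0.22), and Ifi27l2a by 2.21 (SE 0.27). Ifit1 was at 1 UMI in the naive brains together and was 38.4 times higher with metastases (95% counting interval 6.71 to 1534), and Rsad2, at 2 UMIs, was 28.9 times higher (7.84 to 241). Cxcl10, which attracts T cells and NK cells through Cxcr3, rose from 92.8 ± 51.1 to 644 ± 309 CPM (log2 3.06, SE 0.43, adjusted p = 2.1e-06). Its counts were 5 and 5 UMIs in the naive brains and 160 and 44 with metastases. Of the 3 measured interferon gamma genes 2 rose, Cxcl10 among them, and Irf8 fell (log2 -1.36, SE 0.26). The list did not pass (camera adjusted p = 0.377, 0.705 with an estimated correlation; 2 higher and 1 lower over the list alone), but did without naive 2 (adjusted p = 0.0111) and without metastasis 2 (0.0267). Among 11 measured chemokines, 7 rose and 1 fell, or 7 and 3 when adjusted over the list alone (median log2 1.18, camera adjusted p = 0.00911, adjusted p = 0.284 with an estimated correlation). The risers included Ccl5 (log2 1.78, SE 0.29), which attracts T cells, Ccl6 (1.86, SE 0.27) and Ccl9 (1.66, SE 0.27), and Ccl3 fell (-1.04, adjusted p = 2.2e-04). The chemokine list lost its call in each other choice of cells: adjusted p = 0.894 without other types' markers, 0.102 with at most 2 UMIs of them, 0.575 in the cluster with all 11 markers and 0.0813 in the authors' cluster 12. The monocyte markers rose with these genes, as given for the homeostatic list, and the Cxcl10 level depended on which cells were taken. In cells without a UMI of other types' markers (35, 16, 11 and 11 cells) it was 4, 2, 0 and 0 UMIs, or 86.5 unscaled CPM in naive brains against a limit of 120 with metastases. With at most 2 such UMIs it was 5, 2, 26 and 1 UMIs, and in the cluster with all 11 markers 2, 5, 1 and 1. In the authors' cluster 12 it was 2, 5, 17 and 29 (log2 3.94, adjusted p = 0.00224; 4.3e-13 to 0.0161 over 10 alternatives). That cluster also held neutrophil markers, at 612 and 32843 unscaled CPM in naive brains and 53.1 and 91.7 with metastases, and Ttr, at 2262 and 7944 against 11831 and 4769. The interferon list stayed past the threshold in the authors' cluster 12 and not in the cluster with all 11 markers (adjusted p = 0.0583; 8.9e-20 to 0.284 over 10 alternatives). Ifitm3 and Ifi27l2a did not keep their calls in every alternative (log2 0.90 to 2.84 over 13 and 0.58 to 3.27 over 12). Nor did Irf8, Ccl5, Ccl6 and Ccl9.

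**Figure D3:**
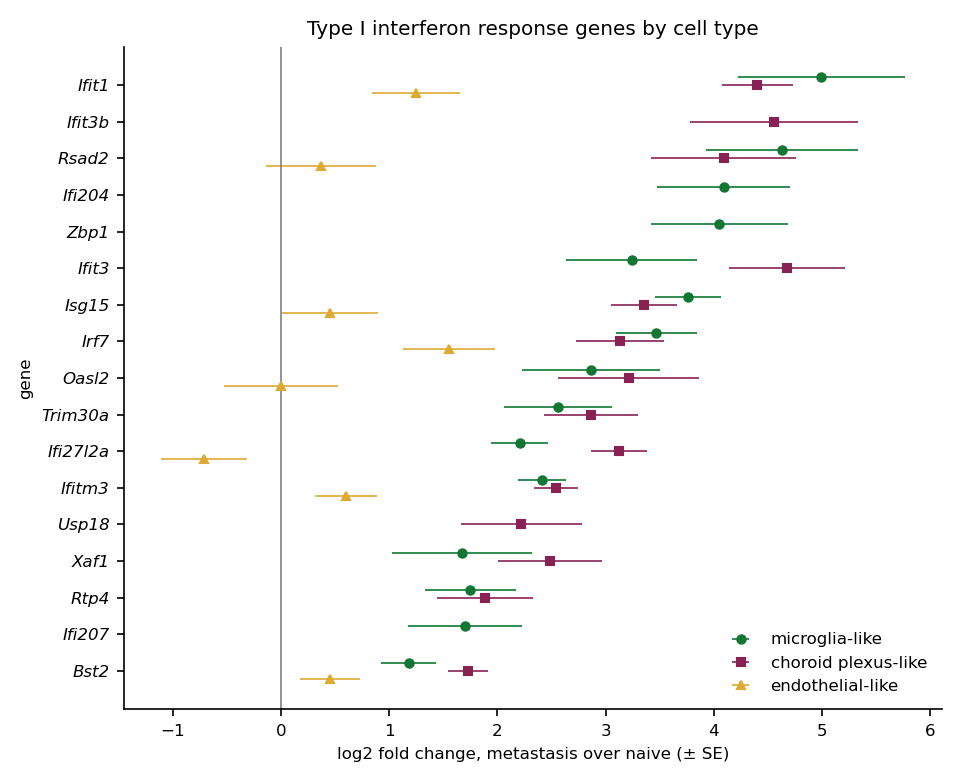
Log2 fold changes (metastasis over naive) of type I interferon genes in microglia-like, choroid plexus-like and endothelial-like cells, with a point and its SE for each measured gene but 1. Medians over all measured genes are 3.05 in microglia-like, 3.13 in choroid plexus-like and 0.45 in endothelial-like cells.

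Cxcl10 UMIs in the brains with metastases were spread over several groups of cells. Of 1105 and 1112 Cxcl10 UMIs in the 2 brains, monocyte-like cells held 20.6% and 22.8%, an unnamed immune cluster led by Ccl8, Ms4a7 and Ccl7 held 23.5% and 25%, and microglia-like cells held 14.5% and 3.96%. The large unnamed clusters held 22.1% and 29.3%, spread over 8306 cells at 5.90 and 6.30 unscaled CPM. Choroid plexus-like cells of the naive brains had 9.30 and 3.29 (4 and 1 UMIs), and the level in the large clusters lay between these. It lay above the 3.26 and 4.58 of choroid plexus-like cells with metastases (2 and 2 UMIs). These counts are too few to set a background, and no share of free RNA was subtracted. Per UMI, Cxcl10 was at 709 and 350 unscaled CPM in microglia-like cells, 574 and 626 in monocyte-like cells and 603 and 305 in the unnamed cluster. Of the 160 and 44 Cxcl10 UMIs of microglia-like cells, the cluster with all microglia markers held 1 and 1 (70.9 and 115 unscaled CPM). The rest lay in the second microglia-like cluster, in which all monocyte markers were detected. Microglia-like cells without a UMI of other types' markers held 0 and 0. Endothelial-like cells had 75.4 and 94.3 and choroid plexus-like cells 3.26 and 4.58. Neutrophil-like cells had 1254 and 447, from 8 and 10 cells.

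**Figure D4:**
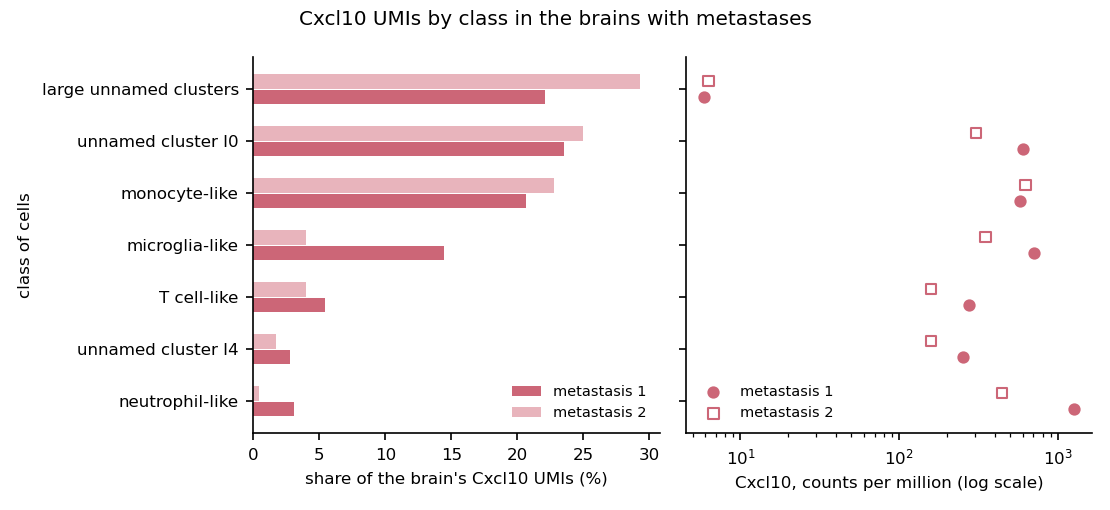
Share of each brain's Cxcl10 UMIs (%, left) and Cxcl10 level (unscaled CPM, log scale, right) by class of cells in metastasis 1 (filled circles) and metastasis 2 (open squares), where clusters I0 and I4 are immune clusters that stayed unnamed. In the right panel the large unnamed clusters are at 5.90 and 6.30 and microglia-like and monocyte-like cells between 350 and 709. Most Cxcl10 UMIs of microglia-like cells lay in their cluster in which all monocyte markers were detected.

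Immune regulators and antigen presentation genes of microglia-like cells moved in both directions. Vsir, which encodes the checkpoint protein VISTA, fell from 1056 ± 148 to 290 ± 40.4 CPM (log2 -1.80, SE 0.24, adjusted p = 9.9e-07), and Entpd1, an enzyme that breaks down extracellular ATP, fell by 1.78 on the log2 scale (SE 0.46). Il1rn, the interleukin 1 receptor antagonist, rose 13.5-fold (interval 3.59 to 114) from 2 UMIs, and Pilra, an inhibitory receptor, 6.02-fold (1.92 to 30.4) from 3. Cd274, which encodes PD-L1, had 1 and 0 UMIs in naive brains and 19 and 8 with metastases, a ratio of 12.2 (2.01 to 499), and was below the low-count filter. Of 7 measured checkpoint and suppressive genes, 3 rose and 2 fell, also over the list alone (camera adjusted p = 0.817, with the median at 0.15 and the test pointing down). MHC class I presentation rose in 8 of 13 genes (9 over the list alone, median log2 0.78, camera adjusted p = 0.00351, adjusted p = 0.284 with an estimated correlation). The proteasome genes led it, with Psme2 (log2 2.01, SE 0.32), Psmb9 (1.90, SE 0.46) and Psmb8 (1.14, SE 0.25), and B2m was at 0.73 (SE 0.21). The list lost its call without other types' markers (adjusted p = 0.0598), in the cluster with all 11 markers (0.133) and in the authors' cluster 12 (0.135). MHC class II presentation rose in 5 of 8 genes, 5 also over the list alone (median 0.80, camera adjusted p = 0.0382, adjusted p = 0.522 with an estimated correlation). Among them were H2-Eb1 (1.12, SE 0.22), H2-DMb1 (1.32, SE 0.34), H2-Aa (0.97, SE 0.24) and H2-Ab1 (0.86, SE 0.23). In the authors' cluster 12, with the neutrophil markers given above in its naive sums, the class II genes turned downward (H2-Eb1 log2 -2.20, H2-Ab1 -2.21, H2-Aa -1.57, H2-DMb1 -0.31; list adjusted p = 0.00105 with the opposite sign, 1.3e-04 to 0.522 over 11 alternatives). H2-Eb1 and H2-Aa were at -0.12 and -0.40 in the cluster with all 11 markers. The class II list lost its call there (adjusted p = 0.122), with RLE scaling (0.0555), by fry (0.277) and without naive 1 (0.0903). Vsir lost its call there (-1.15, adjusted p = 0.137) and in cells without other types' markers (adjusted p = 0.0718), and Entpd1 by DESeq2 (adjusted p = 0.284). Over their alternatives Vsir ranged from log2 -2.24 to -1.15 and Entpd1 from -1.85 to -1.49. The mixture with several immune sources, described below, put Vsir at 301 and 302 unscaled CPM in the brains with metastases. The level seen was 262 and 214, and that of naive microglia-like cells 813. Psmb8 did not keep its call in every alternative (log2 0.13 to 1.52 over 12), nor did Il1rn, Pilra, Psme2, Psmb9 and B2m.

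Inflammatory, lipid and stress genes of microglia-like cells also differed. Il1b, an inflammatory cytokine, rose from 107 ± 41.4 to 1451 ± 191 CPM (log2 3.61, SE 0.31, adjusted p = 2.8e-10), while Icam1, an adhesion molecule, fell (-1.25, SE 0.30). Il1a was at -1.03 (SE 0.37, adjusted p = 0.0354) and at 0.03 without naive 1, and Tnfaip2 was 5.42 times higher (1.71 to 27.5). The list did not pass, with 2 genes up and 2 down, or 2 and 3 over the list alone (camera adjusted p = 0.706). Among 18 disease-associated microglia genes 8 rose and 4 fell, or 8 and 6 over the list alone (median 0.57, camera adjusted p = 0.123; 0.0380 without naive 1, 0.00375 without metastasis 1 and 0.0274 with at most 2 UMIs of other types' markers). Spp1, or osteopontin, rose by 2.98 (SE 0.38), Lgals3, or galectin-3, by 2.64 (SE 0.23), Lyz2 by 1.87 (SE 0.24), and Fabp5 8.43-fold (2.74 to 42.1) from 3 UMIs. Trem2, a lipid-sensing receptor, fell by 1.77 on the log2 scale (SE 0.20). Apoe, a lipid carrier, was at log2 -0.60 (SE 0.32, adjusted p = 0.164) and Axl, a receptor for dying cells, at 0.94 (SE 0.52, adjusted p = 0.184), so neither passed. In lipid handling 6 of 9 genes rose and 1 fell, also over the list alone (median 1.10, camera adjusted p = 0.0702; 0.0184 without naive 2 and 0.011 without metastasis 1), with Lpl 6.47-fold (2.07 to 32.6) and Npc2 at log2 1.00 (SE 0.20). The complement genes C1qa (-1.56, SE 0.21), C1qb (-1.40, SE 0.20) and C1qc (-1.50, SE 0.20) fell and C3 was 7.68 times higher (1.97 to 66.0). Of 8 complement genes 3 fell and 1 rose, also over the list alone (median -0.56, camera adjusted p = 0.0233, adjusted p = 0.284 with an estimated correlation, adjusted p = 0.153 in the cluster with all 11 markers). Dissociation and immediate early genes fell in 14 of 18 and rose in 1, also over the list alone (median -1.38, camera adjusted p = 6.0e-12, adjusted p = 0.284 with an estimated correlation). Among them were Klf2 (-2.42, SE 0.21), Atf3 (-2.10), Jun (-2.06) and Jund (-2.02). Ribosomal proteins were slightly higher (median 0.29, camera adjusted p = 0.0262, adjusted p = 0.499 with an estimated correlation), with Rps27a (0.59) and Rps9 (0.54) past the threshold over all genes and 0 of 20 over the list alone. The ribosomal list lost its call without other types' markers (adjusted p = 0.414) and with at most 2 UMIs of them (0.0753), and by fry the ribosomal, complement and dissociation lists were at adjusted p = 0.0596. In glycolysis and hypoxia 1 of 11 genes rose, also over the list alone, Pkm at 1.43 (SE 0.26; list adjusted p = 0.259, and 2.3e-04 in the authors' cluster 12). Lists with fewer than 3 measured members were not tested. Their measured members were the cell cycle gene Hmgb2 (-0.83, adjusted p = 0.0327), the cytotoxicity genes Ccl5 and Nkg7 (1.70, adjusted p = 0.0199) and the exhaustion genes Lag3 and Entpd1. The regulatory T cell list had Capg (1.43) and the naive T cell list Klf2. The largest rises outside the lists were in genes at 0 UMIs in both naive brains: Thbs1, at least 42.8-fold over the group, Gda, at least 10.8-fold, and Slfn4, at least 10.1-fold. F10 was at least 8.43-fold, Clec4d at least 6.93-fold and Acp5 at least 5.57-fold higher over the group. Cyp4f18 was 25.7 times higher (4.44 to 1034) and Ms4a4c rose by 4.31 (SE 0.37). Thbs1, F10 and Ms4a4c are on the monocyte marker list. Apoe was at 0.13 without metastasis 1 and at -1.71 without metastasis 2, and Lyz2 fell by 2.72 on the log2 scale in the cluster with all 11 markers. Trem2, C1qa, C1qb and C1qc lost their calls there and in cells without other types' markers, where 493 and 322 genes were tested. Over 13 alternatives they ranged from -1.89 to -0.75, -1.80 to -0.23, -1.56 to -0.50 and -1.73 to -0.73. Lgals3, Npc2 and Icam1 did not keep their calls in every alternative (log2 0.84 to 3.18, 0.22 to 1.29 and -1.41 to -0.23). Nor did Lyz2, Il1a, Tnfaip2, Lpl, C3, Jun, Atf3, Rps27a, Rps9, Pkm, Hmgb2, Nkg7, Capg, Acp5 and Cyp4f18. A smaller change was not told apart from fewer counts. The mixture with several immune sources, described below, put Il1b at 1135 and 809 unscaled CPM in the brains with metastases, against 1082 and 1303 seen. It put Lyz2 at 16298 and 10458, against 15434 and 11582 seen.

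Interferon-induced genes were higher in choroid plexus-like cells with metastases, and 0 genes were lower. By edgeR 38 of 4144 genes were higher and 0 lower, and 262 had an unadjusted p under 0.05. DESeq2 gave 11 higher and 0 lower. All 14 measured type I interferon genes rose, 14 also over the list alone (median log2 3.13, camera adjusted p = 1.9e-107, adjusted p = 0.0187 with an estimated correlation). Ifit1, which binds foreign RNA, rose from 13.1 ± 8.49 to 305 ± 15.4 CPM (log2 4.40, SE 0.32, adjusted p = 1.1e-10), and Ifitm3 (2.54, SE 0.20), Ifi27l2a (3.12, SE 0.26) and Isg15 (3.36, SE 0.30) rose too. Ifi44 was 31.4 times higher (5.36 to 1268), Ifit3b 27.2 times (4.61 to 1103) and Ifit3 25.8 times (8.61 to 127), each from at most 3 UMIs. Of 4 interferon gamma genes 3 rose (4 over the list alone; camera adjusted p = 9.3e-13, adjusted p = 0.116 with an estimated correlation). They were the GTPases Gbp3 (30.7 times, 5.23 to 1240), Iigp1 (21.6 times, 3.61 to 882) and Irgm1 (log2 2.88, SE 0.58). MHC class I presentation rose in 5 of 9 genes (7 over the list alone, median 1.62, camera adjusted p = 2.9e-21, adjusted p = 0.116 with an estimated correlation). B2m rose by 1.68 (SE 0.23), H2-T23 by 3.00 (SE 0.45), H2-K1 by 2.15 (SE 0.33) and H2-D1 by 1.62 (SE 0.30). Dissociation genes passed as a list (median 0.51, camera adjusted p = 1.4e-04, adjusted p = 0.392 with an estimated correlation) with 0 of 17 past the threshold over all genes and 2 over the list alone. Other measured lists did not pass: disease-associated microglia (1 of 12 genes, B2m; 2 over the list alone; adjusted p = 0.0730), homeostatic (0 of 3; 1 over the list alone; 0.519) and MHC class II (0 of 3; 0.946, median 0.06 with the test pointing down). Nor did cell cycle (0 of 3; 0.819), ribosomal proteins (0 of 20; 0.708, median 0.00 with the test pointing down), glycolysis and hypoxia (0 of 17; 0.396) and lipid handling genes (0 of 7; 0.708). The last 5 lists had 0 genes over the list alone. Without metastasis 1 the disease-associated (adjusted p = 1.3e-05) and glycolysis lists (0.0447) passed and the dissociation list did not (0.0994). Without metastasis 2 MHC class II passed upward (0.0183) and ribosomal proteins downward (8.1e-05), as they did in clusters found in both conditions (0.0106). By fry the interferon gamma (0.0691), MHC class I (0.238) and dissociation lists (0.238) lost their calls. A cluster led by Gpx3, Chil1 and interferon genes held 1 and 1 naive cells of 143 and 90 and 43 and 41 of 162 and 117 with metastases. Conditions did not overlap for 36 of the 38 genes, and for 36.2% of all genes tested against 33.3% by chance. In the same sums monocyte markers stood at 130 and 132 unscaled CPM in naive brains and 225 and 311 with metastases, plasmacytoid dendritic cell markers at 1261 and 1142 against 1885 and 1922, and endothelial markers at 305 and 352 against 536 and 451. Bst2 is on both the plasmacytoid and the type I interferon list, so the plasmacytoid sum is not independent of the interferon genes. Left with the clusters found in both conditions, 7 genes were higher and 2 lower. Ifitm3 rose (log2 1.08, adjusted p = 4.4e-06) and the interferon list passed (camera adjusted p = 1.7e-22; 1.8e-108 to 0.0358 over 8 alternatives). Calls were lost for Ifit1 (1.92, adjusted p = 0.0969), Isg15 (1.07, 0.552), B2m (0.44, 0.477), H2-K1 (0.91, 0.419), H2-T23 (1.5, 0.477) and H2-D1 (-0.23, 0.943). The interferon gamma genes Gbp3 (log2 4.10 to 7.25), Iigp1 (3.10 to 6.91) and Irgm1 (2.59 to 3.13) did not keep their calls in each of 7 alternatives. Nor did Ifi44 (3.65 to 7.46) and Ifit3b (3.93 to 7.08). Without metastasis 1 the counts were 56 higher and 13 lower.

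Endothelial-like cells, which line blood vessels, differed in few genes. By edgeR 2 of 2266 genes were higher with metastases and 0 lower, and 286 had an unadjusted p under 0.05. Apln, the peptide apelin made by sprouting endothelium, had 0 UMIs in naive brains and 31 and 53 with metastases, at least 16.4-fold over the group (adjusted p = 0.00484). Tubb6, a tubulin, had 4 and 3 UMIs against 31 and 86 (log2 3.24, SE 0.53, adjusted p = 0.0456). Conditions did not overlap for these 2 genes and for 44.5% of all genes tested, against 33.3% by chance. The lists that passed by camera all lost their call with an estimated correlation. Dissociation and immediate early genes went down (0 of 18 genes, 6 over the list alone; median -0.74, adjusted p = 7.6e-08, adjusted p = 0.571 with an estimated correlation). Cell cycle genes went up (0 of 6, 2 over the list alone; median 0.77, adjusted p = 8.2e-04, adjusted p = 0.571 with an estimated correlation), as did ribosomal proteins (0 of 20; median 0.30, adjusted p = 0.00444, adjusted p = 0.710 with an estimated correlation). Type I interferon genes were up as well (0 of 8, 2 over the list alone; median 0.45, adjusted p = 0.0492, adjusted p = 0.571 with an estimated correlation). The interferon list lost its call without naive 1 (adjusted p = 0.228), naive 2 (0.0750) or metastasis 1 (0.481), and had 2.5e-07 without metastasis 2 and 5.7e-08 in clusters found in both conditions. In those clusters the dissociation and ribosomal lists were at adjusted p = 0.762, and the ribosomal list lost its call too without naive 1 (0.0646), naive 2 (0.0750) or metastasis 2 (0.0588). No call was made for MHC class I (adjusted p = 0.974, median -0.02 with the test pointing up), homeostatic (0.974, median -0.17 with the test pointing up), or exhaustion lists (0.974). The same held for the checkpoint (0.102), disease-associated microglia (0.210), inflammatory (0.210), glycolysis and hypoxia (0.485), lipid handling (0.245) and naive T cell lists (0.102), with 0 members past the threshold over all genes in each. Without metastasis 2 the inflammatory (0.0490) and naive T cell lists (0.0191) passed downward, as the latter did without metastasis 1 (0.00374), and by fry no list passed. Ttr, a choroid plexus transcript, stood at 4782 and 4279 unscaled CPM in naive endothelial-like cells and at 14243 and 1553 with metastases. Endothelial markers stood at 16254 and 15914 against 16121 and 9886, and monocyte markers at 342 and 345 against 475 and 704. Microglia markers stood at 719 and 1111 against 1176 and 2334, and the large clusters' genes at 6544 and 7191 against 7894 and 9676. A cluster led by Ctla2a, Apln and Igfbp3 was seen only with metastases (9 and 31 of 115 and 72 cells), and without it neither gene could be tested and 0 genes passed. DESeq2 called 0 genes (Apln adjusted p = 0.134, Tubb6 0.292), and no low-count filter gave 24 higher and 5 lower. Without metastasis 1 the counts were 215 and 173, without metastasis 2 they were 17 and 5, and without either naive brain 4 and 1.

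The response of microglia-like cells was set against those of choroid plexus-like and endothelial-like cells by testing the difference itself. The fits held no term for the brain, although each brain supplied sums of both cell types. List tests on the differences are at the fixed correlation of 0.01 only and were not repeated with an estimated correlation. Choroid plexus-like cells differed from microglia-like cells in 184 of 4953 genes (87 with a higher and 97 with a lower log2 change; 686 with an unadjusted p under 0.05). The interferon list did not differ between them (median difference -0.13 over 27 genes with the test pointing up, camera adjusted p = 0.987). Cxcl10 changed less in choroid plexus-like cells (log2 difference -3.89, SE 1.11, adjusted p = 0.0208), as did Lgals3 (-2.74, SE 0.34) and Lyz2 (-2.07, SE 0.36). Choroid plexus-like cells held 4 and 1 Cxcl10 UMIs in naive brains and 2 and 2 with metastases. Dissociation genes differed in the other direction (median 1.48, 12 of 19 genes higher, camera adjusted p = 2.3e-16), led by Jund (2.46, SE 0.29) and Jun (2.50, SE 0.31). So did the homeostatic list (median 1.79, 2 of 20 genes, Cst3 and Sparc; adjusted p = 0.00316) and the naive T cell list (1 of 3 genes, Klf2; 0.00316). Choroid plexus-like cells alone had 3 measured homeostatic genes, so that difference mostly restates the fall in microglia-like cells. The naive T cell list had fewer than 3 measured genes in either class alone. The difference was negative for ribosomal (median -0.47, camera adjusted p = 3.2e-06) and lipid handling genes (median -1.19, 1 higher and 3 lower of 13; adjusted p = 0.0177). The other lists did not pass (adjusted p of 0.0645 to 0.987). Endothelial-like cells differed from microglia-like cells in 76 of 2983 genes (33 higher and 43 lower; 431 with an unadjusted p under 0.05). The difference was negative for interferon genes (median -2.90, 4 of 16 genes, camera adjusted p = 4.7e-13), with 8 members measured in endothelial-like cells alone. Isg15 was at -3.36 (SE 0.59), Ifi27l2a at -2.97 (SE 0.52), Ifitm3 at -1.87 (SE 0.39) and Rsad2 at -4.27 (SE 1.06). The difference was positive for cell cycle (median 2.12, Hmgb2 and Stmn1; camera adjusted p = 3.3e-05) and homeostatic genes (median 1.74, 2 of 19 genes; adjusted p = 0.00285). Alone, endothelial-like cells had 3 measured homeostatic genes and microglia-like cells fewer than 3 measured cell cycle genes. Each of these differences thus mostly restates the change in the other cell type. A negative difference was found for chemokines (median -1.97, Ccl5 and Cxcl2; adjusted p = 0.00285), MHC class I (-0.62, Psme2; 2.4e-04), MHC class II (-1.33; 0.0113) and disease-associated microglia genes (-0.18, 1 higher and 3 lower of 18; 0.0113). In endothelial-like cells alone, fewer than 3 chemokines and fewer than 3 MHC class II genes were measured. The differences of those lists thus mostly restate the change in microglia-like cells. No other list passed (0.0756 to 0.871). Monocyte markers were higher in the microglia-like sums with metastases, as given above, and enter these differences. For choroid plexus-like cells 36 genes differed without naive 2, at most 85 without any other brain, and 67 with no low-count filter. For endothelial-like cells 25 differed without naive 1, 43 with no low-count filter and 119 by limma voom.

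Within the brains with metastases, microglia-like cells were compared with monocyte-like cells, planned as resident against recruited myeloid cells. Most of these microglia-like cells (85 of 97 and 58 of 66) lay in the second microglia-like cluster, in which all monocyte markers were detected. Its cells had median monocyte marker UMIs of 14 and 7.5 and microglia marker UMIs of 6 and 5. The larger monocyte-like cluster had median monocyte marker UMIs of 10 and 10. Whether the microglia-like cells here were resident cells stays open. Microglia markers defined the classes and overlap the homeostatic list. Of 3938 genes 147 were higher and 95 lower in microglia-like cells (n = 2 brains, brain as a block). Type I interferon genes were lower in microglia-like cells (median log2 -0.53, 4 of 30 genes and 10 over the list alone, camera adjusted p = 5.0e-08, adjusted p = 0.624 with an estimated correlation). Isg20 was at -1.23 (SE 0.25), Ifitm3 at -0.58 (SE 0.05), Ifi27l2a at -0.54 (SE 0.10) and Isg15 at -0.42 (SE 0.08). Cxcl10 did not differ (log2 -0.16, SE 0.22, adjusted p = 0.764), nor did Cd274 (0.07, SE 0.32, adjusted p = 0.948). MHC class II genes were higher (median 0.57, 6 of 10 and 7 over the list alone, camera adjusted p = 6.5e-09, adjusted p = 0.624 with an estimated correlation), with H2-Eb1 at 1.06 (SE 0.08) and H2-Aa at 0.97 (SE 0.07). Inflammatory genes were higher (median 0.54, 4 of 14 and 5 over the list alone, camera adjusted p = 0.00128, adjusted p = 0.624 with an estimated correlation). Il1a was at 3.94 (SE 0.47), the cytokine Tnf at 2.35 (SE 0.32) and Nfkbiz at 1.48 (SE 0.22). Among chemokines Ccl3 (1.94, SE 0.17), Ccl4 (1.66, SE 0.09) and Ccl12 (1.5, SE 0.19) were higher and Ccl6 and Ccl9 lower (-0.45 and -0.42; camera adjusted p = 0.303). Vsir was higher (1.09, SE 0.20) and Il1rn lower (-1.24, SE 0.19) among checkpoint genes (camera adjusted p = 0.847). Homeostatic (15 of 16, 16 over the list alone, median 3.38; adjusted p = 7.3e-42, adjusted p = 0.545 with an estimated correlation) and complement genes (3 of 9; adjusted p = 2.2e-05, adjusted p = 0.624 with an estimated correlation) were higher. Dissociation genes were higher too (12 of 19, 15 over the list alone; adjusted p = 2.8e-24, adjusted p = 0.545 with an estimated correlation). Glycolysis (1 of 16, Pkm; adjusted p = 0.0277, adjusted p = 0.624 with an estimated correlation) and ribosomal genes (2 of 20, 4 over the list alone; adjusted p = 0.0404, adjusted p = 0.624 with an estimated correlation) were lower. The remaining lists did not pass: interferon gamma (adjusted p = 0.669), MHC class I (0.763), disease-associated microglia (0.763; 3 higher and 6 lower of 20), cell cycle (0.353), lipid handling (0.206), exhaustion (0.191) and cytotoxicity (0.763). With at most 2 UMIs of other types' markers per microglia-like cell the inflammatory (adjusted p = 0.199), glycolysis (0.198) and ribosomal lists (0.151) lost their calls, and the cytotoxicity list passed upward (0.0482). The monocyte markers stood at 6487 and 5203 unscaled CPM in the microglia-like sums of these brains, and DESeq2 called 37 list members.

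Surface CD45, a leukocyte protein that is low on resting microglia, was higher on microglia-like cells with metastases. Its centred log-ratio was 1.55 ± 0.0930 in naive brains and 2.67 ± 0.0504 with metastases (SD, n = 2), with median tags of 14 and 14.5 against 167 and 160. The integrin CD11b stood at 2.67 ± 0.101 and 2.98 ± 0.0555, with median tags of 58 and 36.5 against 206 and 214.5, and CD86, a T cell costimulator, at -0.324 ± 0.00238 and -0.197 ± 0.0606. CD25, CD3e and CD4 had median tags of 0 or 1. The 6 comparisons each gave an exact two-sided permutation p of 0.333, the smallest possible (adjusted p = 0.545), so none passed. CD45 on choroid plexus-like cells was 0.0603 ± 0.00375 and 0.154 ± 0.0143 and on endothelial-like cells 0.106 ± 0.0314 and 0.0615 ± 0.148 (exact permutation p = 0.333 and 1). In the cluster with all 11 markers the median CD45 tags were 13 and 14.5 in naive brains and 51.5 and 17 with metastases, and in the second microglia-like cluster 188 and 174 with metastases. Tag depth moved with them: median hashing tags of a cell's own brain were 64 and 32 against 113.5 and 163 in the first cluster, and 544 and 818 with metastases in the second. In the cluster with all 11 markers CD11b was lower with metastases (-0.452) and CD86 too (-0.324). Over all microglia-like cells CD11b was lower as a share of a cell's tags on the log2 scale (-0.384).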

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

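All tests of mixed droplets, free RNA and the choroid plexus-like cluster were chosen after the results were seen, while the test of hashing tags was set before its result was seen. The response to metastases differed between cell types by a test of the difference itself: 184 genes for choroid plexus-like against microglia-like cells (87 higher and 97 lower) and 76 for endothelial-like against microglia-like cells (33 higher and 43 lower). The causes of these differences between cell types were not tested.

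The first pattern is the fall of homeostatic genes and the rise of interferon genes in microglia-like cells, where monocyte markers rose in the same sums, but little in the cluster with all 11 markers (736 and 263 to 567 and 920 unscaled CPM, 12 and 8 cells with metastases), in which T cell markers went from 99.5 and 243 to 780 and 345 and the form with several sources below left homeostatic genes at -0.152 and -0.413. For the homeostatic fall, a larger share of free RNA with metastases is argued against, since Ttr and the large clusters' genes stood at 0.821 times their naive level. Free RNA was common to all brains of the pool, so the test could show only a difference in its amount per droplet. RNA of other cells in the same droplets could not be told apart from a change within microglia: mixing naive microglia-like RNA with monocyte-like RNA left homeostatic genes at -0.452 and -0.836 log2 and interferon genes at 0.212 and 0.186 in the 2 brains, and in cells with at most 2 UMIs of other types' markers, chosen for few UMIs of some of the same monocyte genes, -1.04 and -1.19, and 0.897 and 1.12. A second form with several immune sources, chosen after the first was seen, left -0.117 and -0.157, and 0.105 and 0.0682, with -0.100 and -0.0798, and -0.0224 and 0.378 in the cells with few such UMIs, so the answer turns on which sources are allowed. Over all microglia-like cells, the first form took 65.3% and 55.0% of the RNA as monocyte-like. The second took 25.7% and 26.0% as naive microglia-like RNA. A simulated 4-fold homeostatic fall at 30% microglia left -1.75, below the -0.117 and -0.157 seen with several sources. A simulated 4-fold interferon rise left 0.104 (0.724 at 70%), so at a low microglia share the test could hardly show such a rise. Microglia that share monocyte genes would be counted as other cells' RNA, and a biological change with metastases stays open as a hypothesis.

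The second pattern is the rise of interferon genes in choroid plexus-like cells. A larger share of free RNA with metastases is argued against, because the genes of the large clusters moved by 0.0888 log2 and 6 abundant immune transcripts by -0.154 while the summed interferon genes moved by 2.49. The test reaches no further, because free RNA of the pool was common to the 4 brains. The large clusters' genes were also at most 1.22 log2 above other cells. A single cluster is argued against as the whole cause, because without it the median of the interferon genes was 1.21 with 14 of 14 above 0, against 3.08 with all clusters, so that cluster carries a large part. A response of this epithelium to the metastases may be present, as a hypothesis found and tested on the same 4 brains. Other differences between the procedures the mice went through were not tested, nor was monocyte RNA in the same droplets, whose markers went from 130 and 132 to 225 and 311 unscaled CPM.

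The third pattern is that 102 cells of the large unnamed clusters carried the hashing tag of a naive brain. Wrong assignment had the values it needs: the highest other tag was that of a brain with metastases in 99.0% of these cells (95% interval 94.7 to 99.8) against 89.4% (87.0 to 91.3) of other cells assigned to naive brains. Their assigned tags had a median of 11 and the highest other tags 36.5, against 39 and 5 in the other cells. The same rates would put 1.55 and 0.451 wrongly assigned cells among the 61 and 24 naive microglia-like cells, and 6.66 and 1.94 against the 2 and 4 naive monocyte-like cells seen. By these rates alone, part or all of the naive monocyte-like cells could be due to wrong assignment. Their assigned tags had a median of 137.5 and the highest other tags 9, and naive microglia-like cells 66 and 4. The tag pattern of the 102 cells was thus not seen in these medians. Droplets holding a cell and naive debris stay open, and no biological explanation was tested.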

How the results depend on the processing

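The alternatives with at most 2 UMIs of other types' markers, the cluster with all 11 markers alone, clusters found in both conditions, cells outside the large clusters, T cell-like cells without a cluster, list tests in other cell types and the response differences were chosen after the data were seen. Causes of the changes below were not tested, except that fewer cells or fewer genes tested lower a count. Among single genes, lists and other named values, 515 alternatives kept the direction and the side of the threshold, 151 lost the call, 5 gained it and 16 changed sign. With a brain left out these numbers were 443, 59, 14 and 3. The median of all genes in microglia-like cells shifted by 0.244 log2 by DESeq2, 0.289 with no low-count filter, 0.121 without naive 1, -0.119 with equal cells and -0.138 with equal depth.

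Genes higher and lower in microglia-like cells (278 and 282) were 127 and 52 by DESeq2, 92 and 102 with equal cell numbers and 117 and 152 at equal depth. They were 14 and 20 in cells without other types' markers, 18 and 40 in the authors' cluster 12, 53 and 86 with at most 2 UMIs of those markers and 10 and 25 in the cluster with all 11 markers. With no low-count filter they were 358 and 138. Lists past the threshold (8) were 0 with an estimated correlation, 4 by fry, 4 in cells without other types' markers and 3 in the cluster with all 11 markers. Apoe was at 0.69 without other types' markers and 0.25 with at most 2 UMIs. In the authors' cluster 12 H2-Eb1 was at -2.20, H2-Ab1 at -2.21, H2-Aa at -1.57 and H2-DMb1 at -0.31, with the sign of the MHC class II list at -1. In the cluster with all 11 markers that sign was -1 too, and H2-Eb1 was at -0.12, H2-Aa at -0.40, H2-Ab1 at -0.48, Lyz2 at -2.72, Il1a at 0.14, Hmgb2 at 0.12 and Rps9 at -0.0076.

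In endothelial-like cells DESeq2 and the clusters found in both conditions gave 0 higher genes, RLE 1 and no filter 24, with 5 lower. Their lists past the threshold (4) were 0 with an estimated correlation, 0 by fry and 1 in clusters found in both conditions. In choroid plexus-like cells DESeq2 gave 11 higher, no filter 1 lower, and clusters found in both conditions 7 higher and 2 lower with H2-D1 at -0.23. Lists there (4) were 1 with an estimated correlation and 1 by fry. Between microglia-like and monocyte-like cells 37 list members passed by DESeq2 and 0 lists with an estimated correlation. Response differences were 67 for choroid plexus-like and 43 for endothelial-like cells with no filter, and 119 for the latter by limma voom with duplicateCorrelation.

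Differences in shares changed sign for NK-like (0.486 points) and mixed clusters (2.58) outside the large clusters and for T cell-like cells among immune cells other than microglia (-14.2) and without their cluster with monocyte markers (-0.640). As the log2 share of a cell's tags, CD11b on microglia-like cells was at -0.384, CD25 at 0.963, CD3e at 0.2804 and CD4 at 0.998. In the cluster with all 11 markers CD11b was at -0.452, CD25 at 0.0519, CD3e at 0.153, CD4 at 0.306 and CD86 at -0.324. As medians over cells CD4 was at -0.00982 on endothelial-like and 0.0439 on choroid plexus-like cells.

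With 1 brain left out at a time, microglia-like genes ranged from 175 to 275 higher and 121 to 192 lower, Il1a from -1.31 to 0.0299 and Apoe from -1.71 to 0.13. Endothelial-like genes ranged from 4 to 215 higher and 1 to 173 lower, with 2 to 5 lists. Choroid plexus-like lower genes ranged from 0 to 13, and the sign of their MHC class II list from -1 to 1. Response differences ranged from 36 to 85 and from 25 to 88. On endothelial-like cells CD4 ranged from -0.00918 to 0.0194, CD45 from -0.149 to 0.0602 and CD86 from -0.00901 to 0.0649, and on choroid plexus-like cells CD11b ranged from -0.00625 to 0.0657 and CD86 from -0.0251 to 0.0585.

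The microglia-like sums held 109274 and 49448 UMIs in the naive brains and 225538 and 125884 with metastases. Genes that fell under the low-count filter in a smaller set of cells have no value there, Cxcl10 among them in cells without other types' markers, with at most 2 UMIs of them and in the cluster with all 11 markers. No paired analysis was possible because each brain belonged to a single condition and no numbering links them.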

Other observations

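No test was run in this part, and the genes below were chosen after their values were seen. Genes of lymphocyte function were counted in T cell-like and NK-like cells of the brains with metastases. In the T cell-like sums there, monocyte markers stood at 5304 and 3703 unscaled CPM and T cell markers at 2513 and 2860. Gzmb, a granule protease, stood at 1030 and 1702 unscaled CPM in NK-like cells (26 and 52 UMIs) and at 300 and 278 in T cell-like cells (65 and 77 UMIs). Tnfrsf4, the costimulator OX40, had 40 and 117 UMIs in T cell-like cells (185 and 423 unscaled CPM), and Pdcd1, the checkpoint receptor PD-1, had 4 and 13. Ifng, the main lymphocyte interferon, had 4 and 9 UMIs in T cell-like and 3 and 3 in NK-like cells. In naive brains these classes held 11 and 3 T cell-like and 4 and 6 NK-like cells.

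Cxcl9, another ligand of Cxcr3, had with metastases 48 and 70 UMIs in the unnamed immune cluster led by Ccl8 and Ms4a7, 13 and 32 in monocyte-like cells, 10 and 4 in microglia-like cells and 10 and 16 in the large unnamed clusters. Cd274, which encodes PD-L1, stood at 109 and 262 unscaled CPM in conventional dendritic-like cells (2 and 10 UMIs), 92.8 and 81.2 in the cluster led by Ccl8, 70.5 and 71.7 in monocyte-like cells and 84.2 and 63.6 in microglia-like cells. Spp1 stood at 554 and 862 in that cluster, 267 and 1068 in monocyte-like cells, 536 and 485 in microglia-like cells and 918 and 6485 in fibroblast-like cells (17 and 183 UMIs). The large unnamed clusters held 529 and 1211 Spp1 UMIs, at 12.8 and 23.4 unscaled CPM.

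A T cell-like cluster of 136 cells seen only with metastases had 10 monocyte markers detected, a median of 2582 UMIs and a median of 209.5 CD11b tags, against 776 UMIs and 2 CD11b tags in the other T cell-like cluster. The unnamed cluster led by Ccl8 and Ms4a7 (422 cells) had a median of 2741 UMIs and 296.5 CD45 tags, and the larger monocyte-like cluster 956.5 UMIs and 64 CD45 tags.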
